A study of Mus musculus with 4 samples.

How the data were processed

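m6A-enriched RNA was analysed in 4 libraries of mouse embryonic stem cells, 2 wild-type and 2 Mettl5 knockout. Groups were taken from the genotype given in the labels. The titles of the wild-type libraries differ in wording, and their labels give the same genotype. Per the labels' protocols, total RNA was fragmented and precipitated with an antibody against m6A before library preparation. The submitters' processing notes name HISAT2, HOMER and the mm10 build without saying what each was used for. The peak caller and its settings are not given in the sources used here, nor is the input against which enrichment was measured.

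The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled samples. Each deposited peak has a position, its exon blocks, a gene, a transcript class, a p-value, its log10 with the log10 of an adjusted p-value, and a fold enrichment, per the file headers. The fold is a ratio to a background that the deposited lists do not name. These values are the authors' own for each peak, and they were used to describe, rank or filter peaks within a list, never to compare a level between lists. The format differed from the annotation tables expected before the data were examined, so the planned transcript classes were replaced by those listed, and the gene listed for each peak was used. Every listed peak lay in an exon class, so peaks in introns or between genes had no part in any comparison. The deposited lists reach down to weak evidence: 22, 25, 238 and 24 peaks in wild type 1, wild type 2, knockout 1 and knockout 2 had an adjusted p-value of 0.05 or more. The p-value was listed as 0 for 860, 1073, 868 and 998 peaks, for which only its log10 keeps an order; 152, 192, 139 and 200 of them had no finite log10 and are tied at the top.

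Peaks off the reference chromosomes (3, 5, 6 and 3) were left out. Peaks of the 4 lists were joined into regions where exon blocks overlapped by at least 1 bp, on either strand. Blocks were chosen over whole spans after seeing that peaks can cross introns. A region or gene was present in a library when a peak of that library lay in it. Strength was the percentile of the p-value within its list, 100 being the strongest, and the best peak stood for a gene. The MeRIP libraries are named as stranded by no source used here: between 5.26% and 5.84% of the peaks of a list overlapped a peak on the opposite strand, and for those the gene is uncertain.

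Presence in both libraries of a genotype and neither of the other was counted and set beside the same counts for the other pairings of the libraries. Of the 16 gene lists, 4 were name patterns (ribosomal protein, translation initiation factor, zinc finger protein and histone genes), which also take in genes of other functions with such names. Gene lists were tested with Fisher's exact test, two-sided, against all 9949 genes with a peak in any library, with Benjamini-Hochberg adjustment over 32 tests. Whether the best peaks of a list were strong within a library was tested by 100000 permutations of its genes, adjusted over 64 tests. Wilson intervals (95%) cover counting error only. The depth per library is unknown here, so the chance that a methylated transcript went unlisted cannot be set for any gene. Named genes followed a rule set before the data were examined: Mettl5, Fbxw7, Myc, Pou5f1, Sox2, Nanog, Klf4, Esrrb, Malat1 and ribosomal RNA genes always; the 10 strongest wild-type-only, the 10 strongest knockout-only and the 10 strongest genes in all libraries, predicted genes left out of the first pair of lists; and up to 4 members of each list in each direction. Ties were broken by fold, a choice made after the data were seen. Other members were named as examples after their values were seen.

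The region counting was tested on simulated lists of 11114 regions with 200 planted regions per direction for the wild-type against knockout comparison. Of these, 99.5% of the wild-type-only and 100% of the knockout-only regions were recovered. The simulated peaks were copies of wild type 1 regions with small shifts, so peaks of differing width were not tried. Other regions were left out of lists at random, and 478 wild-type-only and 476 knockout-only regions were found in all. Recovery therefore does not show that a counted region follows the genotype. Gene symbols were checked against a RefSeq table of GRCm38.p6, which held the symbols of 92.7% of the peaks; 97.8% of those peaks overlapped the gene. The listed symbols Skp1a and Wbscr22 are not current names there, and the peak lists give the non-coding RNA Norad an older symbol, so its peaks were not counted in the list of long non-coding RNAs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Alternatives were a reciprocal overlap of 50%, joining peaks within 100 bp, the stronger 50% of each list, lists of equal length, genes in place of regions, and leaving out each library; added after seeing the data were an adjusted p-value under 0.05, whole spans, the same strand, and strength by fold. Sequence motifs need a genome and were not analysed here.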

Results

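The series mapped N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, in mouse embryonic stem cells with and without Mettl5, the methyltransferase that places an m6A in 18S ribosomal RNA. Fragmented total RNA was enriched with an antibody against m6A and sequenced (MeRIP-seq), and 1 peak list per library was analysed: 2 wild-type and 2 Mettl5 knockout libraries. The lists held 11696 and 11201 peaks in wild type 1 and 2, and 12699 and 10821 peaks in knockout 1 and 2. They named 7771, 7509, 8338 and 7281 genes in the same order. Read depth per library was not analysed here. Nothing in the labels said whether the libraries of a genotype came from separate cultures or clones, so the spread between them may be technical.

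The comparison asked whether the m6A map of the transcriptome differed without Mettl5. Peak number did not separate the genotypes. The mean was 11448.5 ± 350.0 peaks (SD, n = 2) in wild type and 11760 ± 1328 peaks (SD, n = 2) in the knockout, whose libraries lay on either side of both wild-type libraries. The smallest p that a two-sided exact permutation test can give with 2 against 2 libraries is 0.333, so no difference between the genotype means was tested.

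Mettl5 itself, the deleted gene, had no peak in any of the 4 lists, wild type included, so the lists could not check the genotype labels. No peak of a ribosomal RNA gene was among those analysed in any library, so the known target of Mettl5 could not be followed. The Fbxw7 transcript, which encodes the substrate receptor of a ubiquitin ligase, carried a strong peak in all 4 libraries. Its peaks lay in coding exons between positions 84974547 and 84978119 of chromosome 3 (mm10), with the authors' fold enrichment between 830 and 1100. The Myc transcript, whose protein is a substrate of that ligase, had a peak in knockout 1 alone, over its coding exons on chromosome 15, positions 61985540 to 61990284, at a fold of 1020.

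The peaks lay in the same transcript parts in both genotypes. The 3' untranslated region held 38.5% ± 0.146 of the peaks in wild type and 38.4% ± 0.325 in the knockout (SD, n = 2 each). The coding sequence held 35.5% ± 0.0924 and 35.1% ± 1.98, exons with no finer class 21.2% ± 0.0252 and 21.8% ± 1.26, and the 5' untranslated region 4.72% ± 0.114 and 4.59% ± 0.407. Every one of these 4 differences was smaller than the spread between the knockout libraries. Single libraries set their sign: the knockout minus wild-type difference in coding sequence was -0.491 percentage points with all libraries, 0.909 without knockout 1 and -1.89 without knockout 2. In the 3' untranslated region it was -0.0232 with all libraries, 0.0799 without wild type 1 and 0.207 without knockout 2, and negative without either of the others (-0.126 without wild type 2, -0.253 without knockout 1). Protein-coding genes held between 88.0% and 89.6% of the peaks of a library.

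**Figure D1:**
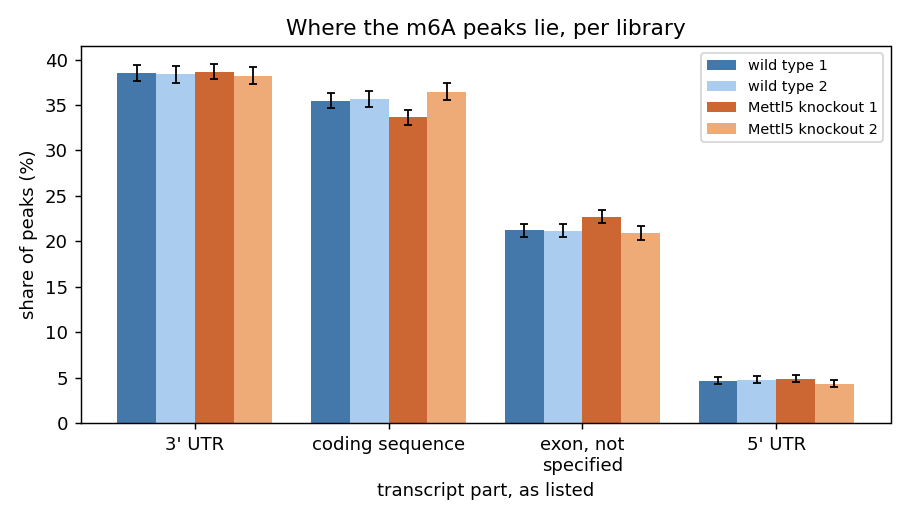
Share of m6A peaks (percent, vertical axis) in each transcript part for the 4 libraries; bars are single libraries and error bars are 95% Wilson intervals, which cover counting error only. The 3' untranslated region held about the same share in every library, and the coding sequence ranged from 33.7% in knockout 1 to 36.5% in knockout 2.

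A large shared map was found in all 4 libraries. Peaks were joined into 15487 regions, of which 6589 (42.5%) had a peak in every library and 4386 (28.3%) in a single library. Of 9949 genes with a peak, 5683 (57.1%) had one in all 4 libraries. The strongest of these, with a mean strength percentile of 99.3 within their lists, were Plec (plectin), Zfp830, Tet2 (a 5-methylcytosine dioxygenase), Exosc6 (a subunit of the RNA exosome), Rbm15 (a component of the m6A writer complex), Ppp4r2, Spen, Crebzf, Map1a and the pluripotency factor Klf4. Their p-values have no finite log10 and tie at the top of each list, so they have no order among themselves. Whether such values mark the strongest peaks was not tested. The peak of the gene Usf1 had no finite log10 in wild type 2, at a fold of 501. In wild type 1 its negative log10 p-value, as the authors list it, was 879 at a fold of 525. Sox2 (99.0) and Esrrb (97.6), also pluripotency factors, and the nuclear non-coding RNA Malat1 (98.5) had strong peaks in every library, that of Malat1 with a peak on the opposite strand as well. Pou5f1 had a weaker peak in each library (fold 1.36 to 7.59), which in wild type 1 lay in another part of the gene than in the other 3 libraries. No peak of Nanog was among those analysed.

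The sharing of regions did not separate the genotypes. The Jaccard index, the regions shared by a pair over the regions found in either, was 0.657 for the wild-type pair and 0.588 for the knockout pair, against 0.615 to 0.646 for the 4 pairs across genotypes. The mean within a genotype was lower by 0.00626 than across, where the SD of the 6 pairs was 0.0247. The sign was not stable. With lists of equal length the difference, within minus across, was 0.00223. It was -0.0440 without wild type 1, -0.0374 without wild type 2, 0.0161 without knockout 1 and 0.0402 without knockout 2.

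Few regions followed the genotype. A peak in both wild-type libraries and in neither knockout library was found in 313 regions, and the reverse in 388. Both together made 701 of the 2318 regions found in exactly 2 libraries, or 30.2% (95% Wilson interval 28.4 to 32.1). The other ways to pair the 4 libraries, which cross the genotypes, gave 837 and 780 regions, and an equal division would give 33.3% each. With all lists shortened to their strongest 10821 peaks, the genotype pairing held 699 regions (34.3%, interval 32.3 to 36.4) and the crossed pairings 660 and 680. The counts leaned on each library, because a genotype was then judged from 1 list. Without wild type 1, wild type 2, knockout 1 or knockout 2, there were 1087, 1359, 1168 and 782 wild-type-only regions, and 885, 806, 1127 and 2308 knockout-only regions.

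**Figure D2:**
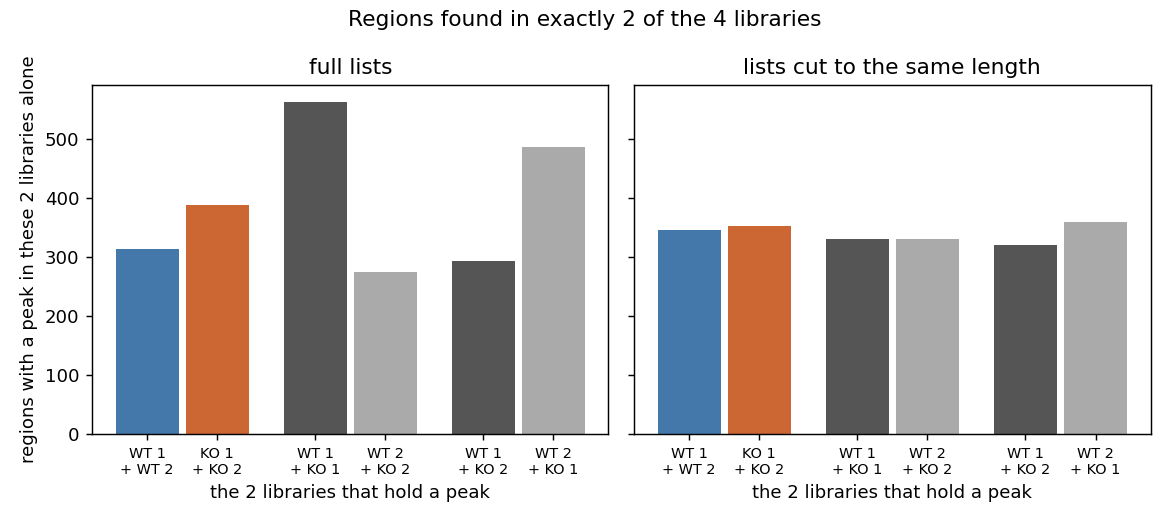
Number of regions (vertical axis) with a peak in exactly the 2 libraries named under each bar, from the full lists (left) and from lists shortened to 10821 peaks each (right); WT is wild type, KO is Mettl5 knockout, coloured bars are the genotype pairing and grey bars the crossed pairings. In the full lists the pair of wild type 1 and knockout 1 shares the most regions (563), and at equal length the 6 bars lie between 320 and 360.

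At the level of genes, 155 had a peak in both wild-type libraries and in neither knockout library, and 226 the reverse. Crossed pairs of libraries gave between 142 and 324 such genes. A gene can be counted here with peaks at different places: 134 of the 155 and 194 of the 226 had a region that itself followed the genotype. The wild-type-only genes with the strongest peaks were Scaf4, which acts in termination of transcription by RNA polymerase II, Usf1 and Zfp24, both transcription factors, Pde12, Fsbp, Mtrr (methionine synthase reductase), Fzr1 (an activator of the anaphase-promoting complex), Zfp260, Cenpj (a centriole protein) and Tspan14. Scaf4 peaks lay in coding exons on chromosome 16, positions 90229077 to 90230242, at folds of 355 and 475, and Usf1 peaks on chromosome 1, positions 171415771 to 171418724, at folds of 501 and 525. The Fsbp region also held a peak assigned to another gene in knockout 1.

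The knockout-only genes with the strongest peaks were Psma4 (a proteasome subunit), Rexo1 (an RNA exonuclease), Prelid3b, Eef2 (the translation elongation factor that drives translocation), Pdia3 (a disulfide isomerase of the endoplasmic reticulum), Zbtb1, Kifc5b (a kinesin), Zfp655, Chd7 (a chromatin remodeller) and Fam222b. The Chd7 peaks of the knockout libraries lay in different regions, with the best ones at positions 8854109 to 8856746 of chromosome 4 in knockout 1 and 8752346 to 8753305 in knockout 2, so no Chd7 region was shared by them. Psma4 peaks lay in coding exons on chromosome 9, positions 54954703 to 54958030, at folds of 32.7 and 55.9. Eef2 peaks lay on chromosome 10, positions 81181517 to 81182468, at folds of 24.9 and 38.8, and Rexo1 peaks on the same chromosome, positions 80547931 to 80551003, at folds of 775 and 1430. These strong cases were exceptions. The best peak reached the strongest 10% of its list on average in 9 of the 155 wild-type-only and 11 of the 226 knockout-only genes. Peaks in wild-type-only and knockout-only regions had median strength percentiles of 25.1 and 24.2, against 24.2 in regions of 2 libraries across genotypes. Regions shared by all 4 libraries had 61.5 and regions of a single library 16.0. The strongest 10% of their list held 5.69% of the peaks in wild-type-only and 7.09% of those in knockout-only regions. For regions of 2 libraries across genotypes it was 4.81%. No test was run on single genes, and absence from a list does not show that the mark was absent. Among the strongest 10% of peaks, 10.2% ± 4.90 (SD over 4 ordered pairs) had no counterpart in the other library of the same genotype.

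**Figure D3:**
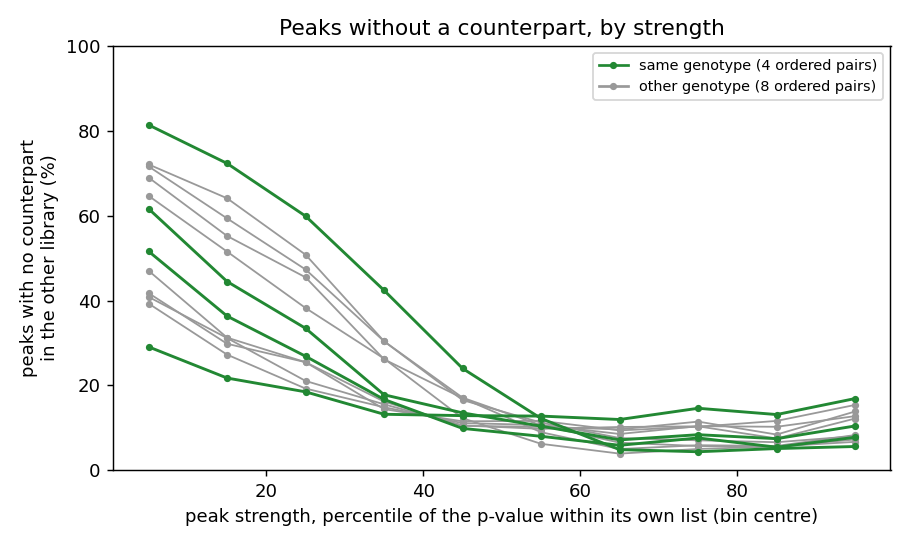
Share of a library's peaks with no counterpart in another library (percent, vertical axis) against peak strength in bins of 10 percentiles (horizontal axis, bin centre); each line is an ordered pair of libraries, 4 within a genotype (green) and 8 across (grey). The mean over the 12 pairs falls from 55.8% in the weakest bin to 7.55% between the 60th and 70th percentiles. It is 10.4% in the strongest. In these end bins the green lines of the wild-type pair lie among the grey ones. Those of the knockout pair lie outside, at 81.4% and 29.1% in the weakest bin, where the grey lines span 39.3% to 72.1%. In the strongest bin they are at 5.59% and 16.9%, where the grey lines span 6.69% to 15.4%.

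No gene list fixed before the data were examined passed a test for a different share of genotype-following genes. Of 32 two-sided Fisher's exact tests (16 lists, 2 directions), 0 passed after Benjamini-Hochberg adjustment and 0 had an unadjusted p under 0.05; the smallest was 0.0745 (adjusted p = 1), for genes named after translation initiation factors, where 2 of 29 members (Eif1 and Eif4a1) were wild-type-only against 0.452 expected. That list is a name pattern and also holds kinases of an initiation factor, such as Eif2ak2 and Eif2ak3, and the binding protein Eif4ebp2. The peaks of Eif1 and Eif4a1 were weak, with folds of 2.6 to 3 and 5.77 to 7.23 and mean percentiles of 30.9 and 29.3. Under-representation could be seen for zinc finger protein genes alone, since the other 15 lists expected fewer than 1 member in each direction. These tests compare the 4 libraries, not the conditions. Single libraries changed the outcome. Without knockout 1, zinc finger protein genes were under-represented among wild-type-only genes (6 against 22.6 expected, Fisher's exact test, adjusted p = 0.00103). Without knockout 2, they were under-represented among knockout-only genes (12 against 33.4, Fisher's exact test, adjusted p = 0.000475), and long non-coding RNAs were over-represented among wild-type-only genes (4 against 0.565, Fisher's exact test, adjusted p = 0.0293). These 4 were Meg3, Rian, Mirg and Firre; the first 3 are neighbours on chromosome 12, which the test counts as independent genes.

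In this and the next paragraph, list members are counted out of those with a peak in any library. With members lacking any peak, the lists held 30 pluripotency genes, 20 genes around Fbxw7, 38 chromatin regulators and 29 m6A writers, erasers and readers. Of 21 pluripotency genes with a peak, 16 had one in all 4 libraries, among them Sox2, Klf4, Esrrb, Fgf4 and Tdgf1. None was wild-type-only, and Tet1 was knockout-only as a gene. Its peaks lay in different regions, in the 3' untranslated region in knockout 1 (fold 4.41, percentile 26.0) and in the coding sequence in knockout 2 (fold 106, percentile 92.6). Of 14 members of the list of Fbxw7, its substrates and its complex, 11 had peaks in all libraries, including Jun, Nfe2l1 and Notch1, and Mtor was knockout-only. Of 30 chromatin regulators, 17 were shared by all libraries, including Kmt2d, Ep300, Crebbp and Tet3, and Tet1 and Chd7 were knockout-only, neither in a region common to both knockout libraries. Of 17 m6A writers, erasers and readers, 11 were shared, including Virma, Rbm15, Ythdc1 and Zcchc4, the methyltransferase of 28S ribosomal RNA, as was Trmt112, the partner protein of Mettl5. None followed the genotype. Of 323 zinc finger protein genes, 258 were shared, 4 were wild-type-only (Zfp24, Zfp260, Zfp119b and Zfp354b) and 7 knockout-only (among them Zfp655, Zfp72, Zfp930 and Zfp874a).

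Signalling genes of the FGF, WNT and TGF-beta pathways had peaks in all libraries in 18 of 26 cases, among them Ctnnb1, Apc and Fzd7. The integrated stress response list had 9 of 15, with Atf4, Trib3 and Ppp1r15a. Ribosome biogenesis genes had 10 of 15, with Ncl and Nop58, ribosomal protein genes 8 of 25, histone genes 6 of 15 and long non-coding RNAs 8 of 13. Markers of cells other than stem cells had peaks too, though many had none. These lists held 26 neural genes, 26 mesoderm and endoderm genes, 20 feeder fibroblast markers and 20 markers of primitive endoderm and trophoblast. In all libraries were 9 of 14 neural genes, with Sox1 and Nes, 7 of 12 mesoderm and endoderm genes, 5 of 8 feeder fibroblast markers and 3 of 9 markers of primitive endoderm and trophoblast. Of these 4 marker lists 1 member followed the genotype, Col4a1, a knockout-only gene with weak peaks (folds of 4.48 and 8.81).

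**Figure D4:**
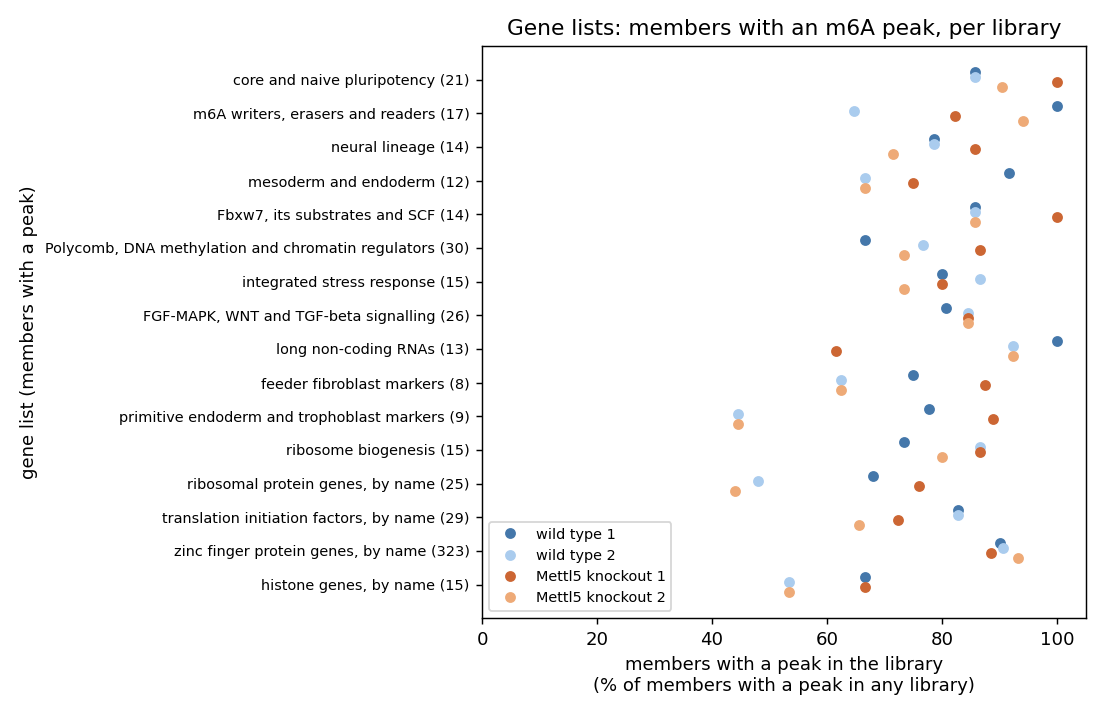
Members of each gene list with an m6A peak in a library, in percent of the members with a peak in any of the 4 libraries (horizontal axis; their number is in brackets); each dot is 1 library. Both wild-type dots lie to one side of both knockout dots in 2 of the 16 lists (pluripotency and genes named after translation initiation factors), where chance gives 33.3% of lists without ties, and the list of long non-coding RNAs is lowest in knockout 1, with 8 of 13 members.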

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

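The alternatives using an adjusted p-value under 0.05, whole spans, the same strand or strength by fold, the count of genes with a region of their own, and the share of regions that follow the genotype, were chosen after seeing the data. None of the results tried under these alternatives carried a call with all libraries, and the permutation calls on gene group strength were not tested under any. The Jaccard difference changed sign without a knockout library and with lists of equal length (0.00223). The genotype differences in transcript parts changed sign too: coding sequence from -0.491 to 0.909 without knockout 1, and the 3' untranslated region from -0.0232 to 0.0878 at equal length, 0.212 by base pairs, 0.0799 without wild type 1 and 0.207 without knockout 2. The stronger 50% of each list by p-value left 140 wild-type-only, 172 knockout-only and 3601 shared regions, and by fold 154, 200 and 3406. Genes in place of regions gave 155 and 226. For these counts and for the share below, the cause was not tested. Leaving out each library gave 782 to 1359 wild-type-only regions, 806 to 2308 knockout-only regions, a Jaccard difference of -0.0440 to 0.0402 and 0 to 2 gene list calls. The share following the genotype was 34.3% with lists of equal length, the only alternative that moved it beyond its interval. Of the 30 genotype-following genes named, 30 remained with an adjusted p-value under 0.05, 29 at equal length, 27 when a region of the gene had to follow the genotype itself (all but Fsbp, Chd7 and Tet1) and 24 in the stronger 50% of each list. No paired analysis was possible because the labels of the wild-type libraries carry no replicate numbers and no result comes from a fitted model. The nearest-gene assignment, the exonic peaks alone and the motif alternatives were not run, since the lists have no such column or hold exonic peaks throughout, and no genome was used here. Depth is unknown here, so it cannot be said which missing peaks were missed for lack of reads.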

Other observations

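The tests of strong peaks, of list length and of the Meg3 cluster below, and the gene group strengths, were chosen after the data had been seen. Some gene groups carried strong peaks in every library. Strength is a rank of the p-value, which can part from the fold. Rpl41 had a mean percentile of 97.8 with a highest fold of 15.2, and Isl1 51.6 with 76.9. RNA levels were not analysed here, so a strong group cannot be read as a more methylated one. Many genes of a list recur in the 4 libraries, so passing in several of them is not independent support. The best peak of a chromatin regulator had a median percentile of 91.1 to 94.3 in the 4 libraries, where the median of all genes was 59.1 to 59.9 (permutation tests, adjusted p of 0.00616 or less in 4 of 4 libraries). Kdm6b, which removes methyl groups from histone H3, and Kmt2b and Kmt2a, which add them, stood at mean percentiles of 98.9, 98.0 and 97.3. Zinc finger protein genes had medians of 73.3 to 78.4 (adjusted p = 0.00016 in 4 of 4 libraries, from the smallest p the permutations can give, 1e-05). Pluripotency genes had medians of 80.1 to 90.1 and passed in 2 of 4 libraries, as did the integrated stress response (83.1 to 90.3) and ribosomal protein genes (66.5 to 93.3). The last passed in wild type 2 and knockout 2, where 12 and 11 members had a peak. They did not pass in wild type 1 and knockout 1, where 17 and 19 had one. Ribosome biogenesis genes (83.6 to 90.2) passed in 1. Feeder fibroblast, mesoderm and endoderm, and primitive endoderm and trophoblast lists lay below all genes in 4 of 4 libraries, with no adjusted p under 0.05. For primitive endoderm and trophoblast the gap in wild type 2 was small (58.8 against 59.1, with 4 members). That list shares Gata6, Pdgfra and Eomes with the mesoderm and endoderm list, so these lists are not independent. A gene with many peaks has more chances of a strong one. With the mean over peaks, for which no p was computed, the median of all genes was 49.7 to 50.2. The excess over it was smaller in every library for the lists that had passed in 4 of 4, 7.05 to 8.22 in place of 14.2 to 18.5 percentile points for zinc finger genes, and 11.6 to 21.2 in place of 32.0 to 34.5 for chromatin regulators. Long non-coding RNAs, which passed in no library, also had a smaller excess in every library (-3.30 to 18.7 in place of 15.2 to 29.9), below all genes in wild type 1 (-1.71) and knockout 2 (-3.30). The excess was larger in every library for ribosome biogenesis (30.4 to 35.0 in place of 24.5 to 30.3), and moved both ways for the integrated stress response (20.05 to 34.8 in place of 24.0 to 30.4), pluripotency genes (17.3 to 25.1 in place of 20.2 to 31.0) and ribosomal protein genes (6.86 to 20.4 in place of 6.66 to 34.2).

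Several regulators with strong peaks were listed in some libraries and missing from others, across genotypes. Zc3h13, a subunit of the m6A writer complex, and Mettl16, another m6A methyltransferase, had mean percentiles of 98.9 and 97.5 in wild type 1 and knockout 2 and no peak in the other libraries. Suz12 (97.5) and Mtf2 (98.3), of the Polycomb repressive complex, had peaks in knockout 1 alone, Eif3a (98.3) in wild type 2 alone and Axin2 (91.5) in knockout 2 alone.

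The share of peaks with no counterpart in another list fell from 55.8% in the weakest 10% to 7.55% between the 60th and 70th percentiles, the bin with the lowest mean, picked after it was seen, and was 10.4% in the strongest 10%, higher in 12 of 12 ordered pairs of libraries. In that strongest 10% it was 1.04 times as high across genotypes as within a genotype (10.6% ± 3.36 against 10.2% ± 4.90, SD over 8 and 4 ordered pairs). Peaks missing within a genotype argue against loss of Mettl5 as the main cause. The within values come from 2 pairs of libraries. The knockout pair gave both the lowest and the highest share of the 12 (5.59% and 16.9%), so a smaller part due to genotype could not be seen. In the strongest 10%, peaks of several exon blocks lacked a counterpart more often than 1-block peaks (14.4% against 7.79%). The rise was seen among 1-block peaks in 8 of 12 pairs. It was absent in the 3 pairs that start from knockout 1 and from wild type 2 to wild type 1 (5.43%, then 5.27%). Both kinds of peaks rose in 3 of 12 pairs, with several-block peaks going from 17.7% to 14.4% on average. Weakness in their own list is excluded by the choice of these peaks, which are its strongest 10%. Whether the same sites lay near the calling threshold in the other list cannot be seen here. Several-block peaks lacked a counterpart more often in 12 of 12 pairs. In the 3 pairs that start from knockout 1, both kinds fell while all peaks together rose. That takes a larger part of several-block peaks in the strongest 10%. On average 1-block peaks went from 6.41% to 7.79%, a smaller rise than that of all peaks. Block structure therefore made up some of the rise. Whether it made up all of it stays undecided, since 1-block peaks rose too in 8 pairs. On average 52.5% of the missing strongest peaks belonged to genes with no peak in the other library, against 53.0% between the 60th and 70th percentiles. A step of the peak caller, which no source used here names, stays open untested.

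Knockout 1 had the longest list and 1913 regions of its own, against 1027 in the next library. With lists of equal length these were 1060 and 855, which left 23.1% of the excess, so a list that reaches further down may account for most of it. Loss of Mettl5 is argued against by the other knockout list, the shortest, with 10821 peaks against 11201 in the shorter wild-type list. Predicted genes made up 20.8% of knockout-only and 11.0% of wild-type-only genes, against 14.8% of all genes with a peak. Among the genes shared by a crossed pair of libraries alone they made up 11.9% to 23.5%, highest for wild type 2 and knockout 1.

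Meg3, Rian and Mirg, neighbouring imprinted non-coding RNAs on chromosome 12, had 4, 3 and 8 peaks in wild type 1, wild type 2 and knockout 2 and 0 in knockout 1; the choice of this cluster was made after its values were seen. A scan for runs of neighbouring genes absent from knockout 1 alone gave a permutation p of 0.026 with Gm26906 counted as a further gene. Its peak is the Meg3 peak on the other strand, and with 1 gene counted per region the run of 3 had a permutation p of 0.361. Counted this way the longest run was 3 genes in each of the 4 libraries, so the scan could not single out a joint loss of 3 genes. Whether these genes were lost together or one by one stays open. The peaks in knockout 2, 8 in number, argue against loss of Mettl5. Whether knockout 1 had less of these RNAs stays open, since RNA levels were not analysed here.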
